A study of Mus musculus with 12 samples.

How the data were processed

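RNA-seq of polyadenylated transcripts was made from mouse embryos at embryonic day 9.5, per the labels' protocols, from about 500 ng of RNA with paired reads of 75 bp. The 12 libraries form 6 groups of 2, by the labelled p53 genotype (wild type or knockout) and by time: untreated, 1 h or 3 h after 30 Gy at 5 Gy per minute. The authors deposited TPM (transcript abundances scaled to a fixed sum within each library) for 53647 gene IDs. The deposited TPM columns sum to between 999999.1 and 1000000.8, so they were scaled within each library and keep no depth. The submitters' processing notes name STAR 2.7.3a, HTSeq 0.12.3, RSEM 1.3.3, DESeq2 1.42.1 and R 4.3.3, without saying which step each did. The annotation release, the strand setting and any read filter are not given in the sources used here. TPM from transcript quantification divides reads among similar genes, so values of close paralogs and pseudogenes are uncertain, and reads of overlapping genes may not be separable.

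Gene symbols were taken by gene ID from a mouse reference annotation of an earlier genome build than the one the submitters name. It matched 52093 IDs (97.1%), and 42 of the tested genes have no symbol. No coordinates of that annotation are given, because the builds differ. It was used besides for transcript GC content, length and gene type in 1 check.

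Genes with a TPM of at least 1 in at least 2 libraries were tested, 15535 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(TPM + 1) with 1 mean per group over all 12 libraries, which share an estimate of the spread moderated along its trend with expression. The residual degrees of freedom were 6, and 5 with the replicate block. Each of 11 contrasts was tested two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The contrasts were 1 h and 3 h against untreated and 3 h against 1 h within each label, knockout against wild type at each time, and the difference of the responses at 1 h and at 3 h. No count model was used, since the values are not counts. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

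Fixed gene lists, 36 in number, were written before the data were examined. They cover the title genes, p53 targets (arrest and feedback, cell death, repair and metabolism, and their union), G2 and mitosis, G1/S, inhibitors of cyclin-dependent kinases, FOXO genes, double-strand break repair, immediate early genes, NF-kappaB targets, the unfolded protein and integrated stress responses, heat shock, NRF2 targets, interferon response, replication histones, mitochondrial transcripts and ribosomal proteins. They also cover markers of primitive erythroid cells, adult globin, visceral endoderm, trophoblast, decidua, neural progenitors, neurons, neural crest, cardiac muscle, somites, endothelium, white blood cells, gut endoderm and limb mesoderm, and posterior Hox genes, sex-linked genes and neighbours of Trp53. They were tested with camera of limma at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over 385 tests of 35 lists. No decidua marker passed the filter. Of these tests 132 passed, and 31 of the 132 held with an estimated correlation, which is given beside each list. Results for 2 single genes of these lists are not reported here.

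The genes named were chosen by a rule fixed at the same time. Trp53 and the 4 title genes are named in every comparison. To these come up to 8 rising and 8 falling genes with the largest fold change among called genes whose libraries do not overlap between groups, leaving out clone-like names. From each list come up to 4 called members with the smallest p, or 2 where none was called.

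The numbers 1 and 2 of the libraries come from the labels. Libraries with the same number deviated together from their group means: the correlation of these deviations across genes lay between 0.327 and 0.796 in all 15 pairs of groups, and 6664 genes differed by number, 4876 higher and 1788 lower in libraries numbered 2. A fit with the replicate number as a block was therefore set beside the fit without it. The 2 libraries of a group correlated at 0.935 to 0.974 across genes, with at most 1.10% identical values, so none was counted as a copy. On simulated data for the comparison of 3 h with untreated libraries labelled knockout, the fit without the block recovered 29 of 100 genes changed 2-fold and 67 of 100 changed 4-fold, with 0 false calls. With the block it recovered 67 and 88, with 9 false calls (5.49% of its calls). These data were drawn from the model with the block, with an effect of the number common to all groups, which favours that fit. The changed genes were taken from those above a low level. In the data both 1 h libraries numbered 2 stood apart, so these rates may not hold for the calls below.

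The alternatives were a pseudocount of 0.1, no filter on low values, median-of-ratios size factors, quantile normalization, only the groups compared in the fit, no trend of the spread, a fold change of at least 2 as well, the replicate block, and each library left out in turn. After the data were seen, fits without both untreated libraries numbered 2 and without both 1 h libraries numbered 2 were added, each with and without the block. Added then as well were a split of the untreated libraries between the times, the responses by library number, and unchanged groups simulated with the difference between numbers.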

Results

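Transcript abundance was measured in 12 RNA-seq libraries from mouse embryos at embryonic day 9.5. The labels divide them by p53 genotype and by time after irradiation. Embryos labelled p53 wild type and embryos labelled p53 knockout were left untreated or were collected 1 h or 3 h after 30 Gy of X-rays, given at 5 Gy per minute. Each of the 6 groups held 2 libraries. The series title names the genes p21 (Cdkn1a), ccng1, foxo3b (Foxo3 in the mouse) and fbxw7, so the comparisons ask how these genes and other targets of p53 respond to irradiation with and without p53. The values are TPM, transcript abundances scaled to a fixed sum within each library, which keep no read depth. The depth of each library is therefore unknown here, and no counting error can be given. All means below carry the SD of 2 libraries (n = 2). Fold changes are on the log2(TPM + 1) scale, which understates changes of genes with low values. Between 13724 and 14357 genes reached a TPM of 1 in a library. The labels do not say whether the 2 libraries of a group came from separate embryos or litters, and p values measure the spread between these libraries. In 4 of the 6 groups 1 library held Xist and the other held Y-linked transcripts, so those 2 came from different embryos. In the 1 h group labelled wild type and the 3 h group labelled knockout both libraries were of the same sex, and there the spread may be technical.

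Trp53 (ENSMUSG00000059552), the gene that encodes p53, was examined first because it checks the genotype labels. In the untreated libraries labelled knockout it stood at 265 and 79.1 TPM in the libraries numbered 1 and 2. It stood at 250 and 210 TPM at 1 h and at 242 and 220 TPM at 3 h in the libraries labelled knockout. In the libraries labelled wild type it stood at 114 and 211 TPM without treatment, at 114 and 66.8 TPM at 1 h, and at 93.7 and 68.03 TPM at 3 h. The library labelled knockout therefore held more Trp53 transcript than the library labelled wild type in 5 of the 6 pairs of equal time and number. The exception was the untreated pair numbered 2. Trp53 transcript went against the genotype labels in these 5 pairs. The labels were kept as given, and every direction below refers to libraries as labelled. The difference between the labelled genotypes was not past the threshold at any time: the log2 fold change of knockout over wild type was -0.10 (SE 0.535) without treatment, 1.38 (SE 0.535) at 1 h and 1.52 (SE 0.535, limma, Benjamini-Hochberg adjusted p = 0.118) at 3 h. The SE pools the spread of all groups, including the 265 and 79.1 TPM of the untreated libraries labelled knockout. A missed call here does not show equal levels. An allele that is transcribed but makes no protein would not be seen in these values.

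**Figure D1:**
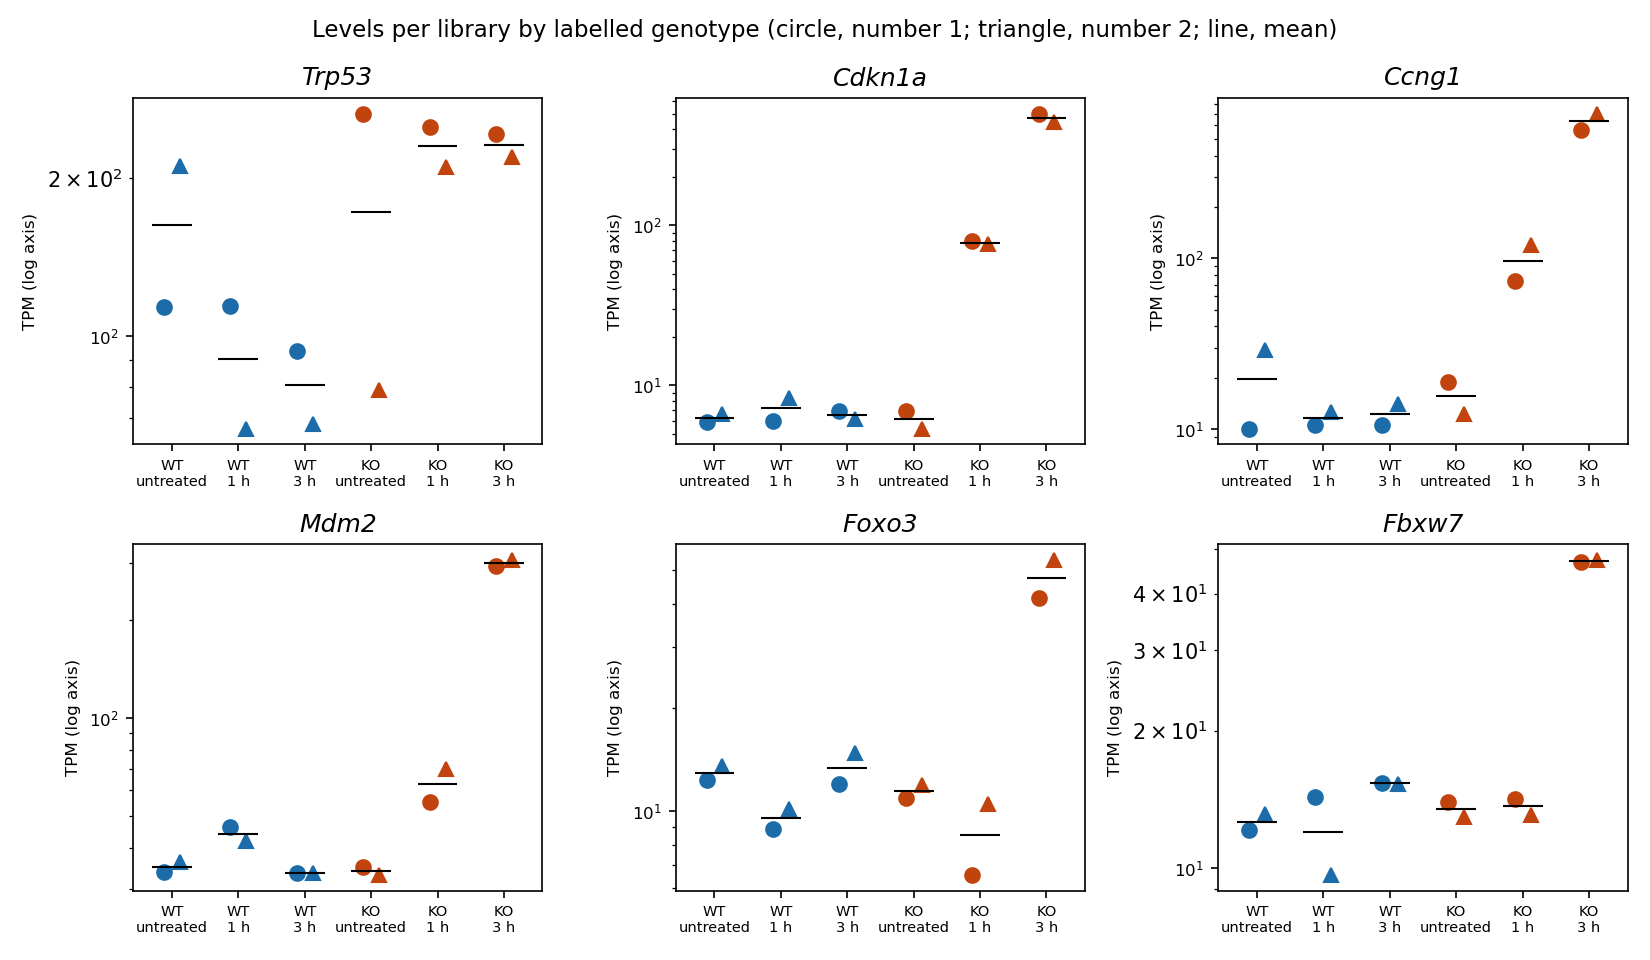
TPM on a log axis of Trp53, Mdm2 and the 4 genes of the series title in each of the 12 libraries, by labelled genotype and time after 30 Gy, with libraries numbered 1 as circles, libraries numbered 2 as triangles and group means as lines. Cdkn1a lies between 5.38 and 8.36 TPM in all libraries except the irradiated ones labelled knockout, where it reaches 79.4 TPM at 1 h and 499 TPM at 3 h.

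At 1 h after irradiation, no gene was called in the libraries labelled wild type, which held the low Trp53 values at that time. The genes of the series title were not called. Cdkn1a, the inhibitor of cyclin-dependent kinases known as p21, was at 6.26 ± 0.488 TPM before and 7.19 ± 1.66 TPM after irradiation (log2 fold change 0.16, SE 0.187). Ccng1, cyclin G1, was at 19.7 ± 13.5 and 11.6 ± 1.37 TPM (-0.54, SE 0.448), with 29.24 and 12.59 TPM in the libraries numbered 2. Foxo3, a forkhead transcription factor, was at 12.9 ± 0.856 and 9.54 ± 0.891 TPM (-0.40, SE 0.232), lower within both numbers, and Fbxw7, a substrate receptor of a ubiquitin ligase, at 12.6 ± 0.728 and 12.0 ± 3.30 TPM. None of the 51 p53 target genes was called, and their median log2 fold change was -0.01. The posterior Hox list of 11 genes was shifted upwards (median 0.95, camera with the preset correlation, Benjamini-Hochberg adjusted p = 7.98e-11). Adjusted p = 0.0963 was obtained with an estimated correlation. Adjusted over the list alone, 6 of its members passed and over all genes 0 did. The neuron list shifted upwards as well (median 0.66, camera adjusted p = 7.54e-10, and adjusted p = 0.267 with an estimated correlation), with 0 of 12 members called and 1 adjusted over the list alone. Across all 15535 genes limma called 0 at an adjusted p under 0.05, while 618 had an unadjusted p under 0.05. With the replicate number as a block, limma also called 0. Without the untreated library labelled wild type numbered 1 it called 2. Both 1 h libraries numbered 2 stood apart from the others on the first principal component, at 67.9 for the label wild type and 66.4 for the label knockout, against -46.1 to 11.8 in the other 10 libraries. Ribosomal protein genes held 19.26% and 19.4% of their TPM, against 11.64% to 13.83% in the others, so the 1 h list shifts of both labels include a library of another composition. Posterior Hox genes were high in the 1 h libraries numbered 1 too. Their mean log2(TPM + 1) was 2.3 to 3.09 in the 1 h libraries of both labels and 0.551 to 2.08 in the untreated and 3 h libraries. A difference of stage between these groups was not tested and cannot be told apart from a response at 1 h.

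At 3 h, genes of G2 and mitosis were lower in the libraries labelled wild type. The list of 27 such genes had a median log2 fold change of -0.67 (camera adjusted p = 1.54e-33, and adjusted p = 0.0363 with an estimated correlation). Plk1, a mitotic kinase, was at 178 ± 18.3 TPM in untreated libraries and at 59.5 ± 3.95 TPM at 3 h (log2 fold change -1.56, SE 0.147, limma adjusted p = 0.0508). Aurka, another mitotic kinase, was at 114 ± 6.92 and 44.3 ± 2.60 TPM (-1.34, SE 0.153, adjusted p = 0.0823). Over all genes tested 0 of the 27 members passed the gene test. Adjusted over the list alone, 13 passed, all lower, and with the replicate block 10 passed over all genes, all lower. With that block Plk1 and Aurka passed, each at an adjusted p of 0.00299. The list of 25 genes of the G1/S transition and replication was shifted upwards (median 0.35, camera adjusted p = 1.26e-10, and adjusted p = 0.0363 with an estimated correlation) with 0 members called. Cdc45, a component of the replicative helicase, was at 47.9 ± 1.70 and 69.6 ± 2.81 TPM (adjusted p = 0.892). Visceral endoderm markers also shifted upwards with 0 of 10 called (median 0.81, camera adjusted p = 0.024, 0.0542 with the replicate block and 0.65 with an estimated correlation). The list no longer passed without a filter, or without the untreated or the 3 h library labelled wild type numbered 2. Apob, one of its genes, was at 1.555 ± 0.502 and 4.555 ± 2.48 TPM.

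The p53 target genes showed no shift at 3 h in these libraries labelled wild type. The median log2 fold change of the 51 genes was -0.01, and Cdkn1a was at 6.57 ± 0.552 TPM, Ccng1 at 12.3 ± 2.41 TPM, Foxo3 at 13.4 ± 1.96 TPM and Fbxw7 at 15.3 ± 0.0566 TPM. The p53 list member with the smallest p was Psrc1, a spindle protein gene, at 51.2 ± 7.01 TPM in untreated libraries and 17.0 ± 0.417 TPM at 3 h (-1.53, SE 0.233, adjusted p = 0.220, and 0.0223 with the replicate block). limma called 0 genes at 3 h, with 524 at an unadjusted p under 0.05. The replicate block raised the count to 24 genes, 1 higher and 23 lower. The count was 1 without either 1 h library labelled knockout or the untreated library labelled wild type numbered 2. Between 3 h and 1 h limma also called 0 genes (928 at an unadjusted p under 0.05). With the replicate block 13 passed, 2 higher and 11 lower. The count was 1 without either 1 h library labelled knockout or either untreated library labelled wild type. The G2 and mitosis list was lower at 3 h than at 1 h (median -0.48, camera adjusted p = 1.5e-18, and 0.0426 with an estimated correlation), with 0 members called, 11 lower adjusted over the list alone and 7 lower with the block. Prc1, a protein of the spindle midzone, was at 94.4 ± 1.98 TPM at 1 h and 45.3 ± 2.78 TPM at 3 h (adjusted p = 0.503, and 0.0238 with the block).

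At 1 h in the libraries labelled knockout, which held the high Trp53 values at that time, 13 genes rose and 3 fell. The largest rises included p53 target genes. Cdkn1a rose from 6.13 ± 1.06 to 77.8 ± 2.25 TPM (log2 fold change 3.47, SE 0.187, limma adjusted p = 0.000498). Sesn2, a stress-induced regulator of mTOR signalling, rose from 9.75 ± 0.594 to 70.9 ± 9.98 TPM (2.74, SE 0.214, adjusted p = 0.00363). Phlda3, an inhibitor of AKT, rose from 6.16 ± 1.27 to 77.3 ± 27.4 TPM, and Pmaip1, which encodes the cell death protein NOXA, rose from 1.56 ± 0.460 to 13.6 ± 2.20 TPM. Inka2, an inhibitor of the kinase PAK4, rose from 1.17 ± 0.269 to 9.33 ± 2.21 TPM. Ccng1 was at 15.6 ± 4.55 and 96.8 ± 33.0 TPM without passing the threshold (2.55, SE 0.448, adjusted p = 0.122, and 0.0308 with the replicate block). The SE of Ccng1 pools the spread of all groups, including 10.09 and 29.24 TPM in the untreated libraries labelled wild type. Foxo3 at 8.54 ± 2.81 TPM and Fbxw7 at 13.6 ± 0.778 TPM did not pass.

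Of the 51 p53 targets, 4 were called higher at 1 h in the libraries labelled knockout, 22 adjusted over the list alone and 14 with the replicate block (median 0.53, camera adjusted p = 4.85e-25, and adjusted p = 0.0713 with an estimated correlation). The 19 targets of arrest and feedback held 3 calls and 12 adjusted over the list alone (adjusted p = 0.0426 with an estimated correlation). Posterior Hox genes, which rise with developmental stage, formed a further group. Hoxc8 rose from 0.865 ± 0.0495 to 15.5 ± 0.198 TPM, Hoxb9 from 11.5 ± 1.21 to 51.8 ± 9.05 TPM and Hoxa9 from 0.535 ± 0.714 to 8.54 ± 0.530 TPM. Over all genes tested 3 of 11 rose, against 10 adjusted over the list alone and 5 with the block (median 1.79, camera adjusted p = 1.74e-21, and adjusted p = 0.0405 with an estimated correlation). Hoxc6, outside that list, rose from 2.41 ± 0.212 to 19.3 ± 1.14 TPM. The same Hox genes were low in the untreated libraries labelled knockout that served as controls here. As they were high at 1 h under both labels, a difference of stage cannot be told apart from a response to irradiation. Otx2, a transcription factor of the anterior neural tube, fell from 50.6 ± 4.19 to 21.2 ± 1.76 TPM. Fzd7, a Wnt receptor, and Efnb2, an ephrin, fell from 75.8 ± 10.9 to 33.1 ± 1.29 TPM and from 55.6 ± 0.0212 to 25.6 ± 0.629 TPM. The neural crest list was shifted downwards (median -0.60, camera adjusted p = 2.51e-05, and 0.0426 with an estimated correlation) with 0 of 9 members called and 6 adjusted over the list alone.

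The 16 calls at 1 h became 142 with the replicate block, 39 higher and 103 lower. With median-of-ratios size factors 70.8% of the calls were higher, against 81.2% as deposited. Without a single library the count was 3 and 4 for the 1 h libraries labelled knockout numbered 1 and 2, and 4 and 2 for the untreated libraries labelled knockout. It was 6 without any one of the 3 h libraries of either label and 8 without either untreated library labelled wild type. Cdkn1a and Hoxc6 kept their calls without any single library, and Sesn2 lost its call without the untreated library labelled knockout numbered 2. Of the other genes named at this time, Hoxc8 and Hoxb9 lost theirs without either 1 h or either untreated library labelled knockout, Inka2 and Pmaip1 without 8 of the 12 libraries, Hoxa9, Phlda3, Otx2 and Efnb2 without 10 and Fzd7 without any. In an alternative chosen after seeing the data, without both untreated libraries numbered 2, no gene was called, with Cdkn1a at an adjusted p of 0.0620. Without both 1 h libraries numbered 2 the count was 5.

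At 3 h in the libraries labelled knockout, where Trp53 was again high, 971 genes rose and 912 fell. Targets of p53 rose together. Of the 51 genes of the p53 target lists 41 rose and none fell (42 adjusted over the lists alone, median log2 fold change 2.41, camera adjusted p = 2.17e-43, and 0.0363 with an estimated correlation). All 4 genes of the series title rose, which is no independent evidence because they were taken from the title. Cdkn1a (ENSMUSG00000023067) went from 6.13 ± 1.06 to 472 ± 38.5 TPM (6.06, SE 0.187, limma adjusted p = 2.27e-06) and Ccng1 (ENSMUSG00000020326) from 15.6 ± 4.55 to 633 ± 98.5 TPM (5.28, SE 0.448, adjusted p = 0.000197). Foxo3 (ENSMUSG00000048756) went from 11.4 ± 0.651 to 47.5 ± 8.52 TPM (1.96, SE 0.232, adjusted p = 0.00106) and Fbxw7 (ENSMUSG00000028086) from 13.4 ± 0.728 to 47.2 ± 0.332 TPM (1.74, SE 0.184, adjusted p = 0.000575).

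Among the targets of arrest and feedback 16 of 19 rose, including Mdm2, the ubiquitin ligase that degrades p53, from 34.0 ± 1.33 to 299.6 ± 8.70 TPM, Sesn2 to 232 ± 35.9 TPM, and Trp53inp1 from 3.63 ± 0.679 to 213 ± 68.5 TPM. Ptprv, a phosphatase gene, rose from 0.0300 to 42.8 ± 9.87 TPM. Among the targets of cell death 11 of 14 rose (adjusted p = 0.0713 with an estimated correlation). Pmaip1 rose from 1.56 ± 0.460 to 228 ± 15.3 TPM (6.49, SE 0.271, adjusted p = 9.85e-06). The death receptor genes Fas, Tnfrsf10b and Eda2r rose from 0.265 ± 0.233 to 44.6 ± 2.66 TPM, from 4.96 ± 0.799 to 79.2 ± 6.35 TPM and from 1.11 ± 1.02 to 93.6 ± 11.1 TPM. Among the targets of repair, metabolism and secretion 14 of 18 rose. Tap1, a peptide transporter, rose from 0.390 ± 0.0707 to 47.6 ± 4.60 TPM, and Ercc5, an excision repair nuclease, from 16.7 ± 2.01 to 83.0 ± 1.82 TPM.

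Cell cycle genes moved in the same libraries labelled knockout. Of the 27 genes of G2 and mitosis, 14 fell and none rose (18 adjusted over the list alone, 25 with the replicate block, median -0.96, camera adjusted p = 6.7e-11, and adjusted p = 0.0839 with an estimated correlation). Plk1 fell from 181 ± 13.2 to 38.5 ± 3.28 TPM (-2.20, SE 0.147, adjusted p = 5.79e-05). Aurka fell from 107 ± 3.75 to 34.1 ± 1.33 TPM, Tpx2, a spindle assembly factor, from 164 ± 12.4 to 47.1 ± 4.07 TPM, and Prc1 from 99.2 ± 8.93 to 27.9 ± 3.37 TPM. Of the 25 G1/S genes only Ccne1, cyclin E1, was called, from 94.7 ± 12.8 to 52.0 ± 0.332 TPM, and the list had no shift (camera adjusted p = 0.611). Among 6 inhibitors of cyclin-dependent kinases 3 rose and 1 fell. Cdkn2b, the inhibitor p15, rose from 0.0350 ± 0.0495 to 4.44 ± 0.594 TPM and Cdkn1b, the inhibitor p27, fell from 28.6 ± 2.29 to 9.69 ± 0.290 TPM. Among 11 FOXO genes 3 rose and 2 fell, with no shift of the list (adjusted p = 0.896). Among them Foxo3 rose as given above. Chek2, a checkpoint kinase gene of the double-strand break repair list, rose from 19.4 ± 0.820 to 43.0 ± 0.134 TPM. Ccne1 lost its call with size factors and without either 3 h library or the untreated library numbered 1 labelled knockout.

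Immediate early genes rose at 3 h in the libraries labelled knockout: 10 of 16 rose and 1 fell (median 0.83, camera adjusted p = 9.41e-08, and 0.0405 with an estimated correlation). Egr1, a zinc finger factor, rose from 2.21 ± 0.0990 to 43.2 ± 9.26 TPM (3.77, SE 0.258, adjusted p = 6.35e-05). Fos rose from 1.45 ± 0.488 to 17.6 ± 1.40 TPM and Atf3 from 8.27 ± 1.98 to 31.0 ± 0.643 TPM. Hmox1, heme oxygenase, was the 1 called gene of 6 NRF2 genes and rose from 16.3 ± 0.665 to 74.0 ± 8.41 TPM. Hspa1a, a heat shock protein, rose from 0.470 ± 0.198 to 6.89 ± 0.912 TPM, and 2 of 9 heat shock genes were called. Of 9 NF-kappaB targets 2 rose, Icam1, an adhesion molecule, from 2.43 ± 0.587 to 14.3 ± 2.55 TPM and Cxcl1, a chemokine listed at 0 in both untreated libraries, to 1.3 ± 0.0707 TPM. None of 11 genes of the unfolded protein and integrated stress responses was called.

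Markers of neural progenitors fell in the libraries labelled knockout at 3 h. Of 13 such genes 10 fell and none rose (11 adjusted over the list alone, median -1.74, camera adjusted p = 7.82e-10, and adjusted p = 0.0560 with an estimated correlation). Olig2, a factor of the ventral spinal cord, fell from 7.82 ± 0.0707 to 0.300 ± 0.0283 TPM (-2.76, SE 0.178, adjusted p = 4.81e-05). Pax6, a factor of the neural tube and eye, fell from 61.8 ± 23.8 to 4.69 ± 0.962 TPM (-3.42, SE 0.403, adjusted p = 0.00102). Sox3 fell from 35.7 ± 1.32 to 4.19 ± 0.219 TPM and Hes5, a Notch target, from 28.6 ± 6.94 to 3.79 ± 1.78 TPM. Outside the lists Dbx1 fell from 13.5 ± 3.90 to 0.545 ± 0.304 TPM and Pou3f2 from 21.4 ± 0.247 to 1.67 ± 0.0141 TPM, both neural transcription factors. Of 9 neural crest markers 5 fell (adjusted p = 0.00688, and 0.110 with an estimated correlation), among them Tfap2b from 16.8 ± 0.601 to 4.51 ± 0.431 TPM. Of 12 markers of early neurons 1 rose and 3 fell, with no shift of the list (adjusted p = 0.0803). Neurod1 rose from 3.45 ± 2.45 to 12.5 ± 2.16 TPM and lost its call without the 3 h library labelled knockout numbered 1. Of 9 gut endoderm markers 4 fell (adjusted p = 0.0206, and 0.154 with an estimated correlation), Foxa1 from 6.53 ± 0.205 to 2.58 ± 0.608 TPM among them. That list was no longer past the threshold with the replicate block (camera adjusted p = 0.0679). Beside these falls, transcripts of red cells rose: 6 of 12 markers of primitive erythroid cells were called higher, 10 with the replicate block (median 1.70, camera adjusted p = 9.1e-07, and adjusted p = 0.328 with an estimated correlation). Their share of TPM was 0.2337% and 0.666% in the untreated libraries labelled knockout and 1.618% and 1.497% at 3 h. Under the label wild type it lay between 0.5404% and 1.318%, so it also varied without a rise of the p53 targets.

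Of the remaining lists, cardiac muscle (3 of 11 higher, median 0.69, camera adjusted p = 0.000379), endothelium (1 of 10 higher, median 0.45, 0.00429), visceral endoderm (0 of 10 called, median 1.94, 0.00042), mitochondrial transcripts (0 of 13, median 0.70, 0.00664) and posterior Hox genes (1 of 11 higher, median 0.54, 0.0172) passed as lists. With an estimated correlation their adjusted p values were 0.180, 0.401, 0.513, 0.129 and 0.510. The posterior Hox list no longer passed without the untreated library labelled knockout numbered 1. NF-kappaB targets passed as well (camera adjusted p = 0.000394, and 0.330 with an estimated correlation). No shift passed for inhibitors of cyclin-dependent kinases (camera adjusted p = 0.0595), double-strand break repair (0.629), unfolded protein and integrated stress responses (0.629), heat shock (0.280), NRF2 targets (0.0528), interferon response (0.211), replication histones (0.824) or ribosomal proteins (0.123). None passed for adult globin (0.178), trophoblast (0.130), somites (0.364), white blood cells (0.261), limb mesoderm (0.114), sex-linked genes (0.806) or neighbours of Trp53 (0.913). The median and the mean differed in sign for heat shock genes, at -0.16 and 0.31. For FOXO genes, at -0.25 and -0.04, and neighbours of Trp53, at -0.06 and -0.01, the median and mean were below 0 and the test pointed upwards.

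The median log2 fold change of all 15535 genes was -0.12 at 3 h in the libraries labelled knockout, and close to 0 with median-of-ratios size factors. The falls named here exceed that shift, and no called list or named gene changed direction with size factors or quantile normalization. With size factors 63.8% of the calls were higher, against 51.6% with the values as deposited. The replicate block raised the count of calls from 1883 to 4534, 1721 higher and 2813 lower. The count was 820 and 983 without the 3 h libraries labelled knockout numbered 1 and 2, and 941 and 955 without the untreated libraries labelled knockout. Without both untreated libraries numbered 2, an alternative chosen after seeing the data, 643 genes were called, 474 higher and 169 lower.

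**Figure D2:**
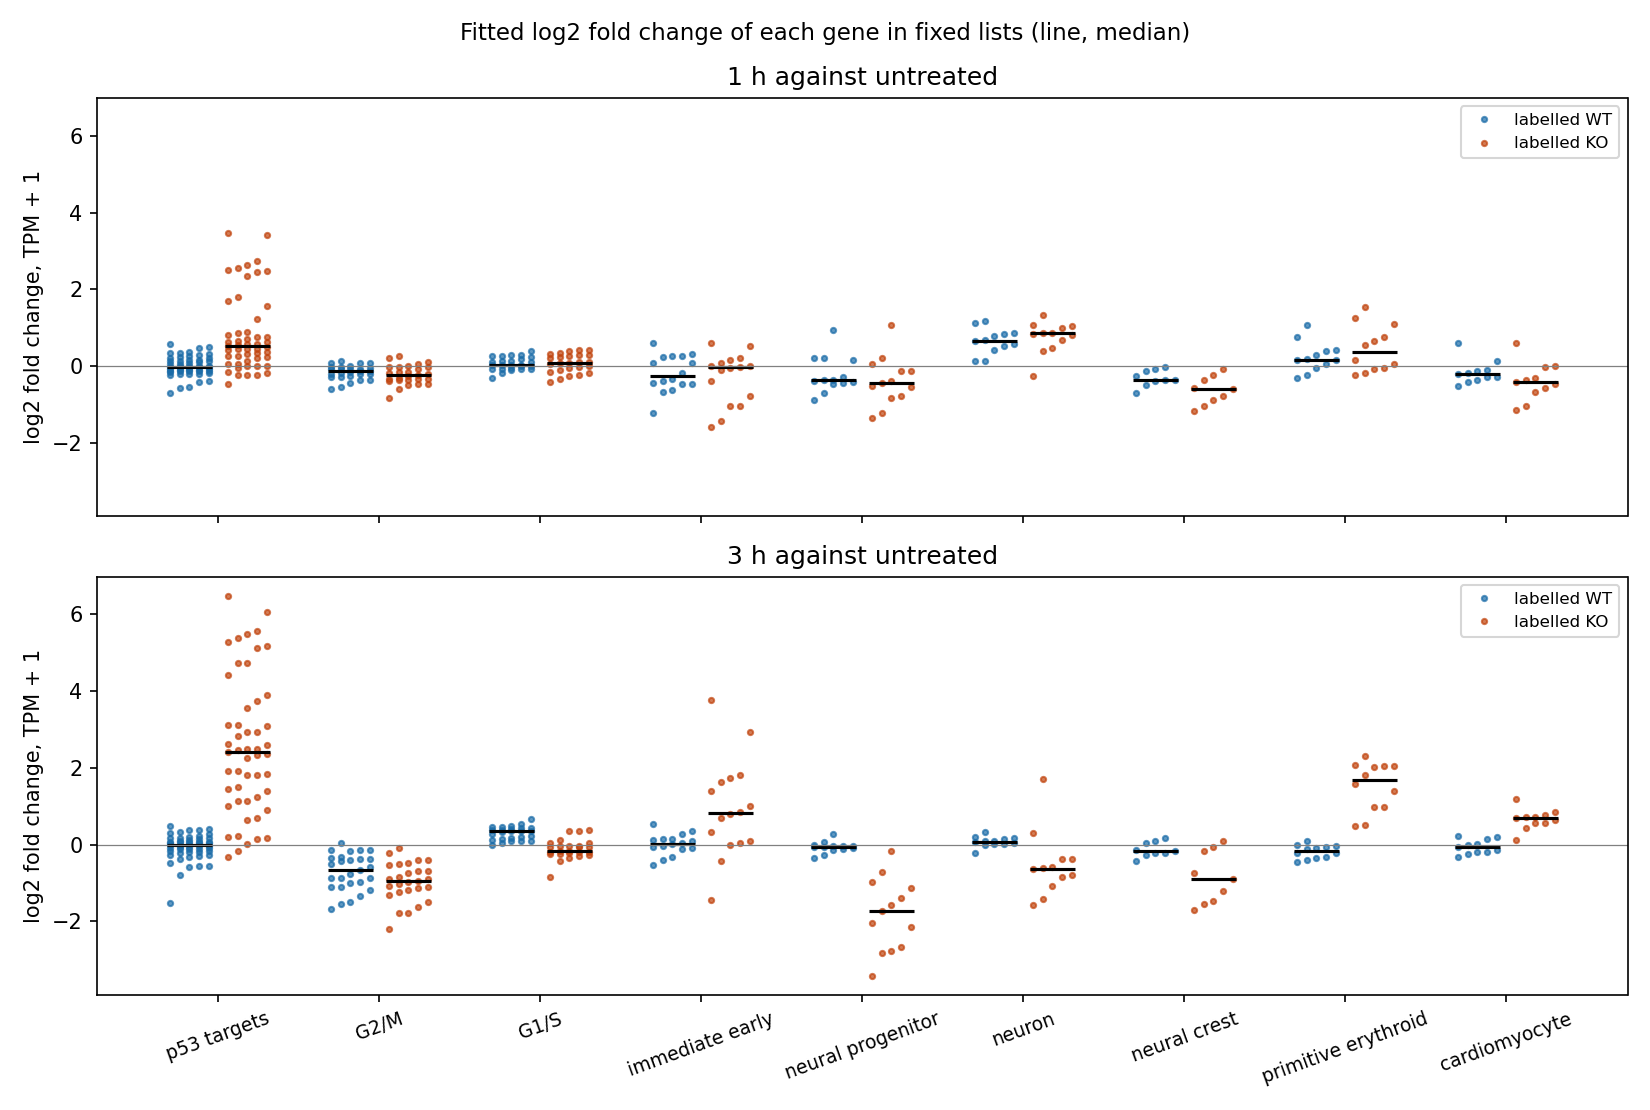
Fitted log2 fold change of TPM + 1 for each gene of 9 fixed lists, at 1 h and at 3 h against untreated libraries, by labelled genotype, with a point per gene and a line at the list median. The median of the p53 target list lies at -0.01 at both times in the libraries labelled wild type and at 0.53 and 2.41 in those labelled knockout.

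Between 1 h and 3 h in the libraries labelled knockout, 1071 genes rose and 669 fell. All 4 genes of the series title rose further: Cdkn1a by a log2 fold change of 2.58 (SE 0.187, limma adjusted p = 9.12e-05), Ccng1 by 2.73 (SE 0.448), Foxo3 by 2.37 (SE 0.232) and Fbxw7 by 1.72 (SE 0.184). Of the p53 targets 35 of 51 rose (39 adjusted over the list alone, median 1.55, adjusted p = 0.0639 with an estimated correlation). Ptprv, Tap1, Fas and Pmaip1 led that group, with log2 fold changes of 4.73, 4.59, 4.43 and 3.98. Immediate early genes rose in 12 of 16 cases (adjusted p = 0.0363 with an estimated correlation), Egr1 by 3.81 (SE 0.258) and Ccn1 by 2.17 (SE 0.142). Of the 27 genes of G2 and mitosis 10 fell, 23 with the replicate block (adjusted p = 0.112 with an estimated correlation). Of 12 early neuron markers 9 fell, among them Tubb3, a neuronal tubulin (-1.62, SE 0.272), and of 13 neural progenitor markers 7 fell. These lists had adjusted p values of 0.399 and 0.0919 with an estimated correlation. Of 11 posterior Hox genes 4 fell (adjusted p = 0.234 with an estimated correlation), with Hoxb9 at -2.12 (SE 0.210). Under the label wild type Tubb3 was likewise higher at 1 h (104.7 ± 22.1 TPM) than at 3 h (59.12 ± 7.28 TPM), without a call. Posterior Hox genes were high in the 1 h libraries of both labels. A difference of stage between the times was not tested and cannot be told apart from a response. The replicate block raised the count of calls from 1740 to 4525, 2076 higher and 2449 lower. It was 1031 and 1052 without the 1 h libraries labelled knockout numbered 1 and 2, and 772 and 723 without the 3 h ones. Ccng1 and Tubb3 lost their calls without the 3 h library labelled knockout numbered 2. Without both untreated libraries numbered 2 the count was 1031 and without both 1 h libraries numbered 2 it was 1057.

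Without irradiation, 3 genes differed between the labelled genotypes, and all were Hox genes. Hoxc6, which is not in the posterior Hox list, was at 11.2 ± 0.0566 TPM in the libraries labelled wild type and at 2.41 ± 0.212 TPM in those labelled knockout (log2 fold change -1.84, SE 0.167, limma adjusted p = 0.0368). Hoxb9 was at 47.5 ± 8.17 and 11.5 ± 1.21 TPM (-1.95, SE 0.210, adjusted p = 0.0498), and Hoxc8 at 9.16 ± 3.70 and 0.865 ± 0.0495 TPM (-2.40, SE 0.259, adjusted p = 0.0498). Of the 11 posterior Hox genes 2 were called lower, 7 adjusted over the list alone (median -1.22, camera adjusted p = 4.56e-24, and 0.0363 with an estimated correlation). Both untreated libraries labelled knockout lay below both labelled wild type for 10 of the 11, where chance gives 16.7% for a single gene. The 11 genes are not independent of each other, so this count is not a test. Some lay near the floor, such as Hoxc10 at 0 and 0 against 0.06 and 0.04 TPM. No gene of the title was called: Cdkn1a was at 6.26 ± 0.488 and 6.13 ± 1.06 TPM and Ccng1 at 19.7 ± 13.5 and 15.6 ± 4.55 TPM. The means of Ccng1 hid opposite differences, each in the direction of Trp53. Under the label knockout it was higher among libraries numbered 1 (18.78 against 10.09 TPM) and lower among those numbered 2 (12.35 against 29.24 TPM). None of the 51 p53 targets was called (median -0.04, camera adjusted p = 0.207). Trp53 was higher under the label knockout among libraries numbered 1 and lower among those numbered 2. The groups may therefore mix p53 states, and this result does not show whether the targets depend on p53 without irradiation. With the replicate block 2 of the 3 calls held, with Hoxc8 at an adjusted p of 0.0527. The count was 0 when either library of any group other than the untreated and 1 h libraries labelled wild type was left out. It was 1 without either 1 h library labelled wild type, and 2 and 0 without the untreated libraries labelled wild type numbered 1 and 2. Without both untreated libraries numbered 2, and without both 1 h libraries numbered 2, it was 0. Hoxb9 and Hoxc8 lost their calls without any one of the 12 libraries and Hoxc6 without 10 of them. limma gave 186 genes with an unadjusted p under 0.05.

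At 1 h after irradiation 6 genes were higher in the libraries labelled knockout than in those labelled wild type and none was lower. Cdkn1a was at 77.8 ± 2.25 against 7.19 ± 1.66 TPM (3.28, SE 0.187, limma adjusted p = 0.000801). Sesn2 was at 70.9 ± 9.98 against 9.82 ± 1.18 TPM, Pmaip1 at 13.6 ± 2.20 against 1.82 ± 0.141 TPM, Tnfrsf10b at 13.0 ± 1.85 against 3.25 ± 0.651 TPM and Inka2 at 9.33 ± 2.21 against 0.975 ± 0.332 TPM. The sixth, Gm37795, an unnamed gene model, was chosen after its values were seen. It stood at 3.04 and 2.12 TPM in the libraries labelled knockout and at 0 and 0.05 TPM in those labelled wild type. Of the 51 p53 targets 4 were called, 18 adjusted over the list alone and 9 with the replicate block (median 0.34, camera adjusted p = 1e-48, and 0.0363 with an estimated correlation). Ccng1, at 96.8 ± 33.0 against 11.6 ± 1.37 TPM, was not called (adjusted p = 0.237), with the spread pooled over all groups, the untreated ones included. The block gave 12 calls, all higher. The count was 2 when either library of any irradiated or untreated group labelled knockout, or either 3 h library labelled wild type, was left out, and 1 without either 1 h library labelled wild type. It was 3 without both untreated libraries numbered 2 and 1 without both 1 h libraries numbered 2. Cdkn1a kept its call without any single library. Sesn2 lost its call without either 1 h library labelled wild type or the 1 h library labelled knockout numbered 2, Inka2 and Pmaip1 without 10 of the 12 libraries, and Tnfrsf10b without any.

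At 3 h, 815 genes were higher and 788 lower in the libraries labelled knockout than in those labelled wild type. The p53 targets were higher as a group: 41 of 51 were called higher and none lower (41 higher and 1 lower adjusted over the list alone, median 2.37, camera adjusted p = 5.46e-47, and 0.0363 with an estimated correlation). Cdkn1a was at 472 ± 38.5 against 6.57 ± 0.552 TPM (5.96, SE 0.187, limma adjusted p = 2.58e-06) and Ccng1 at 633 ± 98.5 against 12.3 ± 2.41 TPM (5.58, SE 0.448, adjusted p = 0.000157). Foxo3 was at 47.5 ± 8.52 against 13.4 ± 1.96 TPM (1.75, SE 0.232, adjusted p = 0.00215) and Fbxw7 at 47.2 ± 0.332 against 15.3 ± 0.0566 TPM (1.56, SE 0.184, adjusted p = 0.00120). Zfp365 was at 102 ± 8.81 against 2.08 ± 0.339 TPM and Ddit4l at 68.7 ± 9.62 against 1.31 ± 0.156 TPM. Gtse1, a microtubule protein that acts on p53, was at 231 ± 48.7 against 22.3 ± 0.290 TPM.

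Single genes of other lists differed at 3 h as well. Immediate early genes were higher in 7 of 16 cases, with Egr1 at 43.2 ± 9.26 against 2.01 ± 0.0636 TPM (adjusted p of the list 0.0363 with an estimated correlation). Neural progenitor markers were lower in 9 of 13 cases (median -1.56, adjusted p = 0.0613 with an estimated correlation), with Olig2 at 0.300 ± 0.0283 against 9.85 ± 1.65 TPM and Pax6 at 4.69 ± 0.962 against 49.8 ± 17.7 TPM. Early neuron markers were lower in 4 of 12 cases (adjusted p = 0.519 with an estimated correlation), with Neurod4 at 0.670 against 6.27 ± 0.884 TPM. Some lists of other cell types had medians above 0. Others held members with lower means, such as Hand2 and Prrx1 of limb mesoderm and Foxa1 and Foxa2 of gut endoderm. Cardiac muscle was higher in 6 of 11 cases (median 1.08, camera adjusted p = 9.41e-08, and 0.0713 with an estimated correlation), primitive erythroid cells in 1 of 12 (median 1.04, 0.000132 and 0.44), endothelium in 1 of 10 (median 0.66, 4.34e-05 and 0.234) and visceral endoderm in 0 of 10 (median 1.28, 0.00614 and 0.595), which no longer passed without the 3 h library labelled knockout numbered 2. Primitive erythroid transcripts made up 1.618% and 1.497% of TPM against 0.5404% and 0.8703%. G1/S genes were lower in 4 of 25 cases (median -0.41, camera adjusted p = 0.000561, and 0.0856 with an estimated correlation), with Ccne1 at 52.0 ± 0.332 against 137 ± 14.8 TPM and Slbp, the histone stem-loop binding protein, at 135 ± 5.76 against 228 ± 7.59 TPM. Of 27 genes of G2 and mitosis 6 were lower, with no shift of the list (camera adjusted p = 0.0756): Plk1 was at 38.5 ± 3.28 against 59.5 ± 3.95 TPM. Plk1 and Slbp lost their calls with size factors, and without 7 and 3 of the 12 libraries taken singly, and Neurod4 without the 3 h libraries labelled knockout numbered 1 or labelled wild type numbered 2. The median of all genes lay at -0.16, and with size factors 68.1% of the calls were higher, against 50.8% as deposited. The replicate block raised the count from 1603 to 4371, 1502 higher and 2869 lower. The count was 646 and 737 without the 3 h libraries labelled knockout numbered 1 and 2, and 585 and 667 without those labelled wild type. It was 955 without both untreated libraries numbered 2.

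The difference between the responses of the labelled genotypes was tested directly, as the change in libraries labelled wild type minus that in libraries labelled knockout, so that a negative value is a greater rise under the label knockout. At 1 h Cdkn1a was the 1 gene called (-3.31, SE 0.264, limma adjusted p = 0.0130). The p53 target list differed in the same direction (median -0.43, camera adjusted p = 1.8e-38, and 0.0410 with an estimated correlation), with 1 of 51 called and 14 adjusted over the list alone. Ccng1 was not called (-3.09, SE 0.634, adjusted p = 0.924), again with the spread pooled over all groups. The block gave 8 calls, all negative. Cdkn1a lost its call without 10 of the 12 libraries taken singly. The exceptions were the 1 h library labelled wild type numbered 2, with 1 call, and the untreated library labelled wild type numbered 1, with 4 calls; the count was 0 without any other library. It was also 0 without both untreated or both 1 h libraries numbered 2.

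At 3 h the responses differed for 536 genes, 403 with a negative value and 133 with a positive one. All 4 title genes were negative: Cdkn1a at -5.995 (SE 0.264, adjusted p = 4.66e-05), Ccng1 at -5.75 (SE 0.634, adjusted p = 0.00209), Foxo3 at -1.91 (SE 0.327, adjusted p = 0.0166) and Fbxw7 at -1.48 (SE 0.260, adjusted p = 0.0190). Of the 51 p53 targets 38 were negative and none positive (41 adjusted over the list alone, median -2.43, adjusted p = 0.0363 with an estimated correlation). Of 13 neural progenitor markers 6 were positive, 10 adjusted over the list alone, with Olig2 at 2.699 (SE 0.252) and Otx2 at 1.67 (SE 0.210), and adjusted p = 0.0560 for the list with an estimated correlation. Of 16 immediate early genes 5 were negative, with Egr1 at -4.10 (SE 0.364), and adjusted p = 0.0403 for the list with an estimated correlation. For the G2 and mitosis list no difference passed (median 0.32, camera adjusted p = 0.0853). The median of all genes lay at 0.15. The block raised the count to 2078, 1148 positive and 930 negative. The count was 280 and 275 without the 3 h libraries labelled knockout numbered 1 and 2, 260 and 308 without the untreated ones, 224 and 249 without the 3 h libraries labelled wild type, and 256 and 228 without the untreated ones. Without both untreated libraries numbered 2 it was 85, of which 82 were negative. Foxo3 and Fbxw7 lost their calls without 6 and 8 of the 12 libraries taken singly, and Cdkn1a and Ccng1 without none.

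The 1 h and 3 h comparisons of each label share their untreated libraries. In the libraries labelled knockout 12 genes were called at both times in the same direction, 10 higher and 2 lower. Independent lists of these sizes would share 0.813 and 0.176 genes, and unchanged groups simulated against the same controls shared 0.01 on average over 100 draws. Unchanged groups yield few calls at either time by design. That simulated count therefore does not show how much of the overlap comes from the shared controls. The fold changes correlated at 0.315 across genes, against 0.5 in the simulation, with a covariance of 0.0999 against 0.103. The count of 12 was 3 without either 1 h library labelled knockout, 4 and 5 without the 3 h ones numbered 1 and 2, and 4 and 2 without the untreated ones. It was 5 without either 3 h library labelled wild type and 7 without either untreated one. In the libraries labelled wild type no gene was called at either time, with a correlation of 0.318 against 0.5 in the simulation and a covariance of 0.0398 against 0.103. That simulation left out the library number, whose effect cancels in these comparisons, so its covariance is too high. Simulated with the number, in a test chosen after the data were seen, unchanged groups gave covariances of 0.0568 for the label knockout and 0.0558 for the label wild type. The observed values lay 0.0431 above and 0.016 below these. Here 0 shared genes were simulated, a count with the same limit as before. A split of the untreated libraries, 1 for each time, was chosen after the data were seen, with the lone libraries assumed to vary like the other groups. With the untreated library labelled knockout numbered 1 for 1 h and numbered 2 for 3 h, 2 genes were called at 1 h, 943 at 3 h and 2 at both, with a correlation of 0.0446 and a covariance of 0.0183. The other way round 4, 954 and 4 were called, at 0.0656 and 0.0254. In the libraries labelled wild type none was called at both times in either split, with correlations of -0.146 and -0.142. The difference between numbers enters the comparisons of a split with opposite signs, which lowers these correlations. Genes are not independent replicates in these correlations. Between the labels, the responses correlated across genes at 0.622 at 1 h and 0.143 at 3 h, and 13 of the 16 genes called at 1 h and 1225 of the 1883 called at 3 h under the label knockout had the same sign under the label wild type. The correlation at 1 h depended on the library number, in tests chosen after the data were seen. It was 0.159 among libraries numbered 1 and 0.771 among those numbered 2, but 0.0548 and 0.153 when libraries of different numbers were set against each other. The difference between the responses of the libraries numbered 2 and 1, which holds no common response, correlated at 0.566 between the labels at 1 h and at 0.0342 at 3 h.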

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

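All tests of explanations in this part were chosen only after the result was seen, while the tests of the difference between the responses were planned. That difference is the change in libraries labelled wild type minus the change in libraries labelled knockout, tested with limma and, for lists, camera. At 1 h it passed for 1 gene, Cdkn1a (-3.31), and for the lists of title genes (median -1.60), p53 targets of arrest and feedback (-0.52) and all p53 targets (-0.43), each with an estimated correlation. At 3 h it passed for 536 genes. The lists past the threshold at 3 h with an estimated correlation as well were the title genes (-3.83), p53 targets of arrest and feedback (-2.66), p53 targets of repair and metabolism (-2.19), all p53 targets (-2.43) and immediate early genes (-0.72).

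Among p53 targets and title genes the 3 h difference was -5.995 for Cdkn1a, -5.75 for Ccng1, -1.91 for Foxo3, -1.48 for Fbxw7, -6.12 for Eda2r, -6.11 for Pmaip1, -5.88 for Trp53inp1, -5.41 for Fas, -5.20 for Ptprv, -4.74 for Tap1 and -3.16 for Mdm2. Dcxr was at -4.99. Immediate early genes were at -4.10 (Egr1), -3.47 (Fos), -1.68 (Atf3) and -1.36 (Ccn1). Neural and patterning genes had positive values: 3.38 for Dbx1, 3.34 for Pax6, 3.02 for Pou3f2, 2.699 for Olig2, 2.69 for Sox3, 2.33 for Fgf15, 2.08 for Nkx6-1, 1.74 for Sox1 and 1.67 for Otx2. Epo was at 2.39, Ccne1 at 1.32 and Pabpc1l2b-ps, a pseudogene, at 3.04.

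The p53 target genes responded in the libraries labelled knockout and not in those labelled wild type. That the 3 h embryos labelled wild type were not irradiated is argued against by their G2 and mitosis list, which was lower than in untreated libraries (camera with an estimated correlation, adjusted p = 0.0363). This does not speak for the 1 h embryos of that label. That the labels are right and the targets rose without p53 is argued against by the median of the targets in the libraries labelled wild type at 3 h, -0.0126 (SE of members 0.0481). This SE belongs to the mean of the members, not to their median. It is taken across genes of the same libraries and does not measure the spread between embryos. The highest of the 51 values was 0.474. An exchange of the genotype labels remains a candidate explanation: in 6 of 6 pairs of equal time and number, the mean of the p53 targets was higher in the library with more Trp53. In the irradiated pairs the higher targets are the pattern to be explained, so their agreement with Trp53 is no independent support. Only the untreated pairs could have gone either way, and they differed in the mean of the targets by only 0.0234 and -0.171. Single targets, chosen after their values were seen, followed Trp53 more clearly there. Labelled knockout against wild type, Ccng1 was at 18.78 against 10.09 TPM and Eda2r at 1.83 against 0.09 TPM in the pair numbered 1, and at 12.35 against 29.24 TPM and 0.39 against 2.81 TPM in the pair numbered 2. By these values the untreated pair numbered 2 would not be exchanged, and each untreated group may hold embryos of both p53 states. The comparisons with untreated libraries and the differences of responses would then rest on mixed controls. Under the label knockout the mean log2 value of the targets was higher by 0.762 and 0.765 in the 1 h pairs. It was higher by 2.5 and 2.6 in the 3 h pairs. A response of the p53 targets under that label alone argues against the labels of these irradiated libraries as given. For the untreated libraries the deposited values alone do not settle the labels.

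Libraries numbered 2 differed from those numbered 1 in a partly shared way in all groups. The correlation of these differences between groups ran from 0.327 to 0.796 and was highest between the 1 h groups of the labels. Their Spearman correlation with GC content was 0.0971 in the 1 h group labelled wild type and -0.113 to -0.205 in the others. GC content is argued against, since the lowest correlation of these differences between groups was 0.331 after the GC trend was removed. Reads shared with pseudogenes, or among ribosomal protein and mitochondrial genes, are argued against by a lowest correlation of 0.413 without these genes. Other paralogs were not tested. The sex of the embryos is argued against by a correlation of 0.376 between the 2 groups whose libraries were of the same sex. The design names no factor behind the number. Apart from sex no biological explanation was tested, and a batch or litter could be behind it.

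Posterior Hox genes were lower in the untreated libraries labelled knockout. Their mean log2(TPM + 1) was 0.551 and 0.877 there against 1.95 and 1.76 under the label wild type. At 3 h it was again lower, at 1.21 and 1.35 against 1.72 and 2.08, and at 1 h the labels overlapped, at 2.3 and 3.09 against 2.61 and 2.95. Scaling of the TPM is argued against by a median difference between labels of -1.196 with the other scaling nearer to 0. p53 status stays open. Posterior Hox means followed the label in both untreated pairs, whereas Trp53 was higher under the label knockout only in the pair numbered 1. The 2 untreated libraries labelled knockout, which differ in Trp53, differed in these genes by a median of -0.111. Their means of 0.551 and 0.877 lay further apart than this median. The SE of the mean difference, taken across genes, was 0.161. If the Trp53 transcript marked p53 status in these libraries, these values would argue against it as the source. Both libraries carry the same label, however, and the transcript does not show p53 status. The overlap at 1 h does not settle it, since those embryos were irradiated. Younger embryos in the untreated group may also be the source, and the neuron list, with an adjusted p of 0.399 with an estimated correlation, cannot tell this apart from other differences between litters.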

How the results depend on the processing

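The fits without both untreated or both 1 h libraries numbered 2, and with the untreated libraries split between the times, were chosen after seeing the data. So were the responses by library number and the simulation with the difference between numbers. All other alternatives were planned. With TPM the depth is unknown, so its limit on the calls could not be given. A group with 1 library left was assumed to vary like the others. The cause of the changes below was not tested, except that leaving out libraries and fitting only the groups compared leave fewer degrees of freedom. The block ended 1 call of a named gene, Hoxc8 between the untreated labels, and 4 list calls: gut endoderm at 3 h in libraries labelled knockout, visceral endoderm at 3 h in libraries labelled wild type, and inhibitors of cyclin-dependent kinases between labels at 1 h and in the difference of responses at 3 h. Of 312 called values of named genes, 311 kept their call with the replicate block, 296 with a pseudocount of 0.1, 289 with size factors, 293 with quantile normalization, 274 without a filter, 304 without a trend, 266 with a fold change of at least 2 and 171 with only the groups compared in the fit. With both untreated libraries numbered 2 left out, 214 kept it, without both 1 h libraries numbered 2, 259, and without a single library 201 to 292. No named gene reversed. Of 132 list calls 31 kept theirs with an estimated correlation, 128 with the block, 131 with a pseudocount of 0.1, 126 with size factors, 117 with quantile normalization, 124 without a filter, 132 without a trend and 118 to 129 without a single library. Lists and the overlap of calls were not run with only the groups compared.

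For the libraries labelled wild type the counts of genes called at 1 h, at 3 h and between 3 h and 1 h were 0. They were 4, 15 and 4 with no filter on low values, with an overlap of 3. At 3 h the count was 4 with size factors, 3 with quantile normalization and 24 with the block, and between 3 h and 1 h it was 13 with the block. With both untreated libraries numbered 2 left out the counts at 3 h and between the times were 1 and 1, or 1 and 2 with the block. Without both 1 h libraries numbered 2 the 3 counts were 2, 1 and 3, or 2, 47 and 10 with the block. Without a single library they lay at 0 to 2, 0 to 1 and 0 to 1.

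For the libraries labelled knockout the counts were 16 at 1 h, 1883 at 3 h, 1740 between the times and 12 shared. With only the groups compared in the fit they were 0, 466 and 143. With a fold change of at least 2 as well, 1132 and 1087 were called at 3 h and between the times. With the replicate block the counts were 142, 4534, 4525 and 86 shared. With both untreated libraries numbered 2 left out they were 0, 643, 1031 and 0 shared, and with the block as well 3276 between the times. Without both 1 h libraries numbered 2 the count was 5 at 1 h, 1057 between the times and 2 shared, and with the block as well 791, 5866 and 3928 with 480 shared. Without a single library they lay at 2 to 15, 820 to 1935, 723 to 1731 and 2 to 11 shared. With the untreated libraries split, 1 for each time, 2 were shared with number 1 at 1 h and 4 with number 2.

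Between the labels 3 genes were called without treatment, 6 at 1 h and 1603 at 3 h. The count at 1 h was 2 with a pseudocount of 0.1, and without a trend the untreated count was 1. With only the groups compared in the fit the counts were 0, 0 and 610. With a fold change of at least 2, 959 were called at 3 h, and with the block 12 at 1 h and 4371 at 3 h. With both untreated libraries numbered 2 left out the counts were 0, 3 and 955, and with the block 0 untreated and 3038 at 3 h. Without both 1 h libraries numbered 2 they were 0 untreated and 1 at 1 h, and with the block 1, 13 and 5803. Without a single library they lay at 0 to 2, 1 to 5 and 585 to 1650.

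The responses differed for 1 gene at 1 h and 536 at 3 h. At 1 h the count was 4 with no filter on low values, 3 with size factors, 3 with quantile normalization, 0 with only the groups compared in the fit and 8 with the block, where 2078 were called at 3 h. With both untreated libraries numbered 2 left out the counts were 0 and 85, and 0 at 1 h with the block. Without both 1 h libraries numbered 2 the count at 1 h was 0, and with the block 3434 were called at 3 h. Without a single library they lay at 0 to 4 and 224 to 484. The number of list tests past the threshold was 31 with an estimated correlation and 123 to 141 without a single library.

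Some list medians, called in the fit to all libraries or in the alternative, changed direction. At 1 h between the labels, leaving out 1 library gave -0.0132 (without the 1 h library labelled knockout numbered 1) to 0.1454 for cardiac muscle and -0.49 (numbered 2) to 1.74 for visceral endoderm. It gave -0.29 (1 h library labelled wild type numbered 1) to 0.52 for ribosomal proteins there and -0.58 to 0.24 (that library) for their difference of responses at 1 h. In libraries labelled wild type at 1 h, ribosomal proteins lay at -0.14 (1 h library labelled wild type numbered 2) to 0.67. Leaving out the untreated library labelled knockout numbered 1 turned 4 medians: primitive erythroid cells at 1 h in libraries labelled knockout (range -0.23 to 0.76) and in the difference of responses (-0.69 to 0.46), and neurons between the untreated labels (-0.85 to 0.052) and in the difference of responses at 1 h (-0.62 to 0.36). Visceral endoderm between the untreated labels lay at -0.75 (untreated library labelled knockout numbered 2) to 1.11. With both untreated libraries numbered 2 left out it was at -1.09, with and without the block, and with the block at -0.0346 at 3 h in libraries labelled wild type. With both 1 h libraries numbered 2 left out it was at -0.76 between labels at 1 h, with and without the block, and ribosomal proteins were at -0.14 at 1 h in libraries labelled wild type, or -0.0846 with the block.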

Other observations

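The values of this part were read after the data were seen. By Xist and 4 genes of the Y chromosome, 6 libraries had Xist above the Y-linked genes and 6 had Y-linked genes above Xist. The lowest mean of the Y-linked genes in the latter was 18.3 TPM and the highest in the former was 0.0325 TPM. In 2 of the 6 groups both libraries were of the same sex: the 1 h libraries labelled wild type had Y-linked transcripts and the 3 h libraries labelled knockout had Xist.

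Markers of maternal tissue were low. Among decidua markers Pgr reached 0.59 TPM and Esr1 0.18 TPM, and Prl8a2 and Prl3c1 were listed at 0 in all libraries. The adult globin gene Hbb-bs lay between 8.54 and 37.95 TPM and Hbb-bt between 0.8 and 20.14 TPM, where reads shared among globin genes limit the values.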
